A study of Mus musculus with 8 samples.

How the data were processed

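Cumulus oocyte complexes came from mice of 21 to 23 days given 5 IU of equine chorionic gonadotropin (eCG) and 5 IU of hCG 44 to 47 h later, and were collected 8 h after hCG. Complexes of 3 animals were pooled per array, for 4 PRhet and 4 PRKO arrays, and biotin-labelled cRNA was hybridised to Affymetrix whole-transcript arrays. The deposited values are log2 signals, 1 per probe set and array. The submitters' notes name Partek without a version, and the background correction, normalization and summarisation are not given in the sources used here. The log base was read from the values, which run from 1.19 to 14.08: as a natural or base 10 logarithm the highest would exceed the 65535 that a 16-bit scanner can record. No scanner files, scan dates or batches were used, and the number of arrays limits the precision of each value.

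The file holds 35556 probe sets and no missing values. The 21789 with exactly 1 gene symbol were tested without a filter on signal, and the 1621 with several symbols and 12146 with none were left out. A gene with several probe sets counted once, by the probe set with the highest mean over the 8 arrays, which gave 19938 genes. Entrez identifiers of 21698 probe sets matched the RefSeq table of assembly GRCm38.p6, and 91 did not. Differences are PRKO minus PRhet in log2 units with moderated standard errors from limma 3.58.1 (lmFit and eBayes, prior degrees of freedom 6.04) in R 4.3.3, two-sided, adjusted by Benjamini-Hochberg over all 21789 probe sets, with an adjusted p under 0.05 as the threshold. No block was used, since replicate numbers count the samples within each genotype. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

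The comparison, its test, the gene lists, the rule for naming genes and most alternatives were chosen before the data were examined. The named genes were Pgr, the 12 largest changes in each direction among genes past the threshold whose genotypes did not overlap, up to 6 members past the threshold and 3 others from each list by size of difference, and the 2 members with the highest signal from each cell type list. The rule gave 142 genes, 60 of them past the threshold, and part of the 82 others are given by value. Of 27 lists, 26 had at least 5 measured genes and were tested with camera (preset correlation 0.01, and again with a correlation estimated for each list) and with fry, adjusted over the lists. They cover genes associated with PR in periovulatory follicles, cumulus expansion, EGF-like ligands, prostaglandins, steroidogenesis, cholesterol synthesis, cytokines, Toll-like receptors and complement, interferon-stimulated genes, hypoxia, glycolysis, proteases, adhesion, exocytosis, proliferation, apoptosis, the circadian clock, steroid receptors, markers of 7 cell types and the neighbours of Pgr on chromosome 9. Erythrocyte markers had too few measured genes. Some genes stand in several lists.

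Alternatives were a replicate block, quantile normalization of the deposited values, centring each array, filters on mean signal, an intensity trend with robust moderation, no moderation, array weights, each array left out in turn, all probe sets, the mean of a gene's probe sets, an adjusted p under 0.1, a fold of at least 2, an estimated list correlation and fry. Oocyte markers, theca and stroma markers, and the first component within genotypes were added as covariates after the data were seen. Gene order came from the same RefSeq table, and adjacent genes were compared with 10000 random placements within deciles of signal. The fit was tested on simulated data with 200 changed genes of 19938: it called 71.6% of those changed 1.5-fold, 97% of those changed 2-fold and 100% of those changed 4-fold, all in the right direction, and 5 of its 184 calls (2.7%) were unchanged genes. It called 0 genes when no change was simulated. The simulated noise was independent between probe sets, so variation shared between genes was not covered.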

Results

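Whole-transcript microarrays measured RNA from mouse cumulus oocyte complexes, the oocyte with its surrounding cumulus granulosa cells, collected 8 h after an ovulatory dose of human chorionic gonadotropin (hCG). One group was homozygous for a lacZ insertion in the progesterone receptor gene (PRKO), and the control group was heterozygous for it (PR+/-, here PRhet). Each genotype had 4 arrays, each array held complexes pooled from 3 animals, and 12 animals were used per genotype. The median log2 signal per array lay between 5.35 and 5.46. Pearson correlations across probe sets were 0.992 to 0.995 within a genotype and 0.989 to 0.992 between genotypes, with no pair of identical arrays. The first principal component held 34.3% of the variance and separated the genotypes, with PRhet arrays at -20.64 to -7.05 and PRKO arrays at 11.54 to 16.95. The number of arrays limits the precision of each value.

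The comparison asked which transcripts of the ovulating complex depend on the progesterone receptor (PR), the nuclear receptor that granulosa cells switch on after the gonadotropin surge. Transcripts of Zbtb16, Slc7a11, Hsd17b11, Epas1 and Tmem100 were between 5.07 and 9.39 times lower in PRKO complexes, and known PR-associated genes such as Adamts1, Cxcr4, Pparg and Snap25 fell with them. Transcripts of Olfml2b, Sfrp2, Lipg, Tnc and Igfbp5 were 2.02 to 2.83 times higher. The hyaluronan and prostaglandin synthase genes of cumulus expansion, Has2 and Ptgs2, had log2 differences of 0.04 ± 0.23 and 0.03 ± 0.24 (SE, n = 4 against 4 arrays, limma) and did not pass the test; this pair was chosen after its values were seen. In all, 582 of 19938 genes (2.92%) passed an adjusted p of 0.05 in limma, 286 higher and 296 lower in PRKO (206 and 308 after quantile normalization of the deposited values). The PRKO and PRhet arrays did not overlap for 567 of the 582 genes, and for 10.2% of all genes, against a chance share of 2.86%. Changes downward were larger, with a median fold of 1.59 against 1.40 upward, and of the 87 genes that also differed at least 2-fold, 75 were lower and 12 higher. By an unadjusted p of 0.05 with a fold of at least 1.5, a looser rule that controls no error rate, 325 genes were listed, 120 higher and 205 lower. The count of 582 was 106 in limma's linear model without moderation, 206 when probe sets without a single gene name were tested too, and 324 with the mean of theca and stroma markers as a covariate. It was 384, 363 and 306 without PRhet replicates 1, 2 and 3 and 337, 301 and 383 without PRKO replicates 2, 3 and 4.

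Pgr itself, the gene that carries the insertion, had a signal of 6.78 ± 0.57 in PRhet and 5.69 ± 0.40 in PRKO (mean log2 ± SD, n = 4 arrays each). The difference of -1.09 ± 0.26 (SE), a fold of 2.13, had an adjusted p of 0.0452 in limma. In PRhet the values for replicates 1 to 4 were 6.09, 7.34, 6.54 and 7.15, and in PRKO they were 5.84, 5.23, 5.54 and 6.17, so the highest PRKO array lay above the lowest PRhet array. A two-sided exact permutation test over 70 arrangements of the 8 arrays gave p = 0.0571, where the smallest possible is 0.0286. Where the probe set lies relative to the insertion is not given in the sources used here. A transcript part outside the insertion may still be read, so this signal is a weak check of the genotype labels. The limma call ended without PRhet replicate 2, 3 or 4 or PRKO replicate 1, 2 or 3, with adjusted p from 0.0660 to 0.130, and with theca and stroma markers as a covariate, with adjusted p 0.0824.

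**Figure D1:**
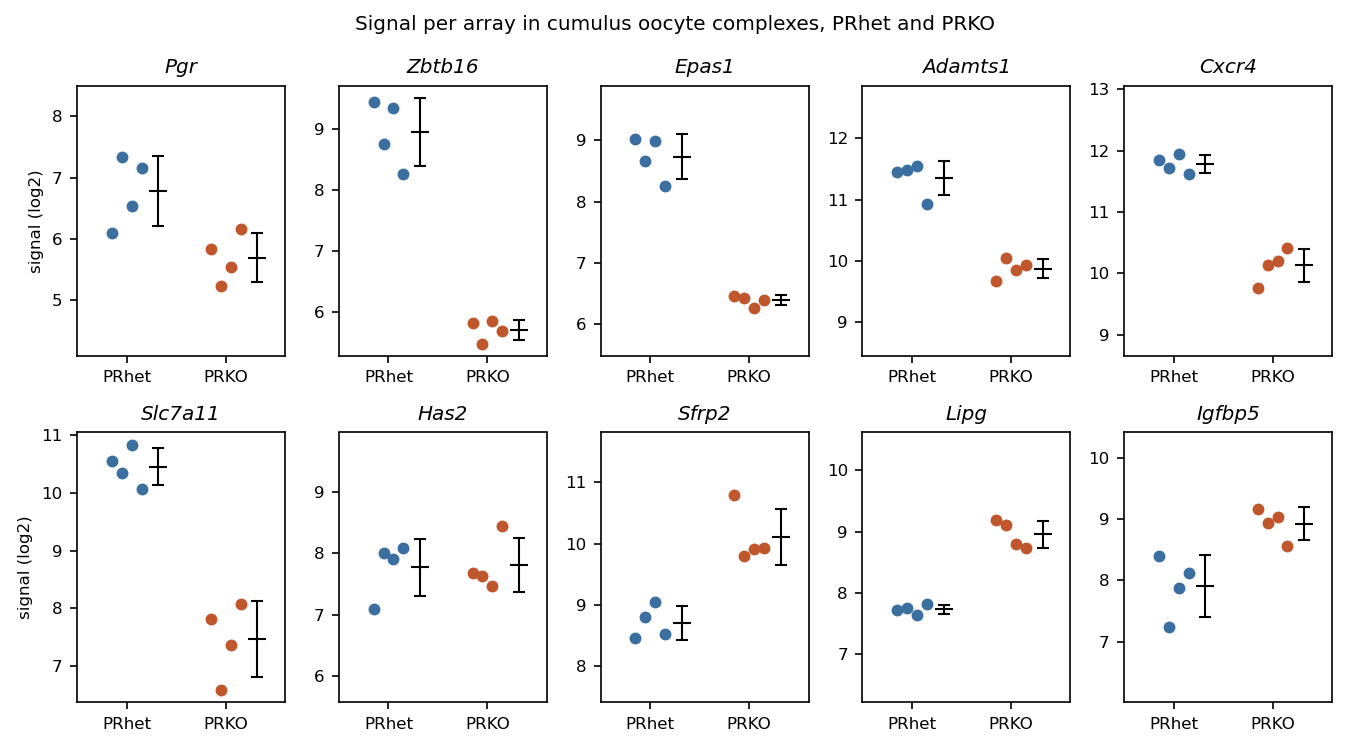
Log2 signal of 10 genes on each array (points) by genotype, with the mean and SD of the 4 arrays of a genotype (black bars); the vertical axes have different origins. Zbtb16, Epas1, Adamts1, Cxcr4 and Slc7a11 lie lower and Sfrp2, Lipg and Igfbp5 higher on each PRKO array than on each PRhet array, Pgr overlaps between 6.09 and 6.17, and Has2 overlaps.

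Among genes lower in PRKO, Zbtb16, which encodes a zinc finger transcription factor, changed most: 8.95 ± 0.55 in PRhet against 5.72 ± 0.17 in PRKO (SD, n = 4), a 9.39-fold difference with a limma adjusted p of 1.92e-05. Slc7a11, the cystine and glutamate exchanger of the plasma membrane, fell by 2.99 ± 0.27 (log2, SE), or 7.96-fold, with adjusted p = 0.000154. Hsd17b11, a short-chain dehydrogenase of lipid droplets, fell by 2.96 ± 0.17, or 7.77-fold, with adjusted p = 7.40e-06. Tmem100, a transmembrane protein gene, fell by 2.47 ± 0.25 and Epas1, which encodes the hypoxia-inducible factor 2 alpha subunit, fell by 2.34 ± 0.15, with limma adjusted p of 0.000233 and 1.43e-05. Gstm1, a glutathione S-transferase, was 4.63-fold lower, Sprr2g 4.17-fold, and Scara5, a scavenger receptor that binds ferritin, 3.97-fold. Tbc1d8 was 3.87-fold lower, Apela, a secreted ligand of the apelin receptor, 3.76-fold, the ephrin gene Efnb2 3.72-fold, and Gpt2, a mitochondrial alanine aminotransferase, 3.70-fold. Limma adjusted p of the genes from Gstm1 to Gpt2 ran from 7.40e-06 to 0.000407, and for each of these 12 genes all 4 PRKO arrays lay below all 4 PRhet arrays. In PRKO the signals of Sprr2g (3.04) and Apela (3.77) lay below the lower quartile of each array (3.92 to 4.00), and with the background unknown their folds may be lower bounds. Gstm1 belongs to a family of like sequences whose members the probe set may read in part.

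Among genes higher in PRKO, Olfml2b, which encodes an olfactomedin-like secreted protein, changed most, from 6.83 ± 0.20 to 8.34 ± 0.36 (SD, n = 4), or 2.83-fold, with a limma adjusted p of 0.000383. Sfrp2, a secreted modulator of Wnt signalling, rose by 1.40 ± 0.20 (log2, SE), or 2.64-fold, with adjusted p = 0.00284. Lipg, which encodes endothelial lipase, rose by 1.22 ± 0.11, or 2.33-fold, and Gm2a, a lysosomal lipid carrier, by 1.13 ± 0.09, or 2.18-fold, with limma adjusted p of 0.000154 and 7.43e-05. The matrix gene Tnc was 2.16-fold higher, the transcription factor gene Msc 2.14-fold, the kinase gene Nuak1 2.09-fold and the actin-binding protein gene Avil 2.06-fold. Rasal1, a Ras GTPase activator, was 2.04-fold higher, and the insulin-like growth factor binding protein genes Igfbp6 and Igfbp5 were 2.04-fold and 2.02-fold higher. Usp17ld, one of a family of near-identical deubiquitinase genes and therefore uncertain, was 2.10-fold higher. Limma adjusted p for these 8 genes ran from 0.000201 for Rasal1 to 0.0493 for Msc, and for all 12 genes named as higher the 4 PRKO arrays lay above the 4 PRhet arrays. The mean of the theca and stroma markers was 0.19 higher in PRKO (95% limits -0.105 to 0.476). With that mean as a covariate Igfbp5, Igfbp6, Tnc, Usp17ld and Msc did not pass, at log2 differences of 0.93, 0.93, 0.80, 0.94 and 1.24, and the limma adjusted p was 0.0800 to 0.153. Calls also ended without PRhet replicate 2 or PRKO replicate 3 for Tnc (up to 0.0665), without PRhet replicate 3 or PRKO replicate 1, 2 or 3 for Igfbp5 (up to 0.0819), without any 1 array other than PRhet replicate 3 for Usp17ld (up to 0.113), and without any 1 other than PRKO replicate 1 or 3 for Msc (up to 0.141).

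**Figure D2:**
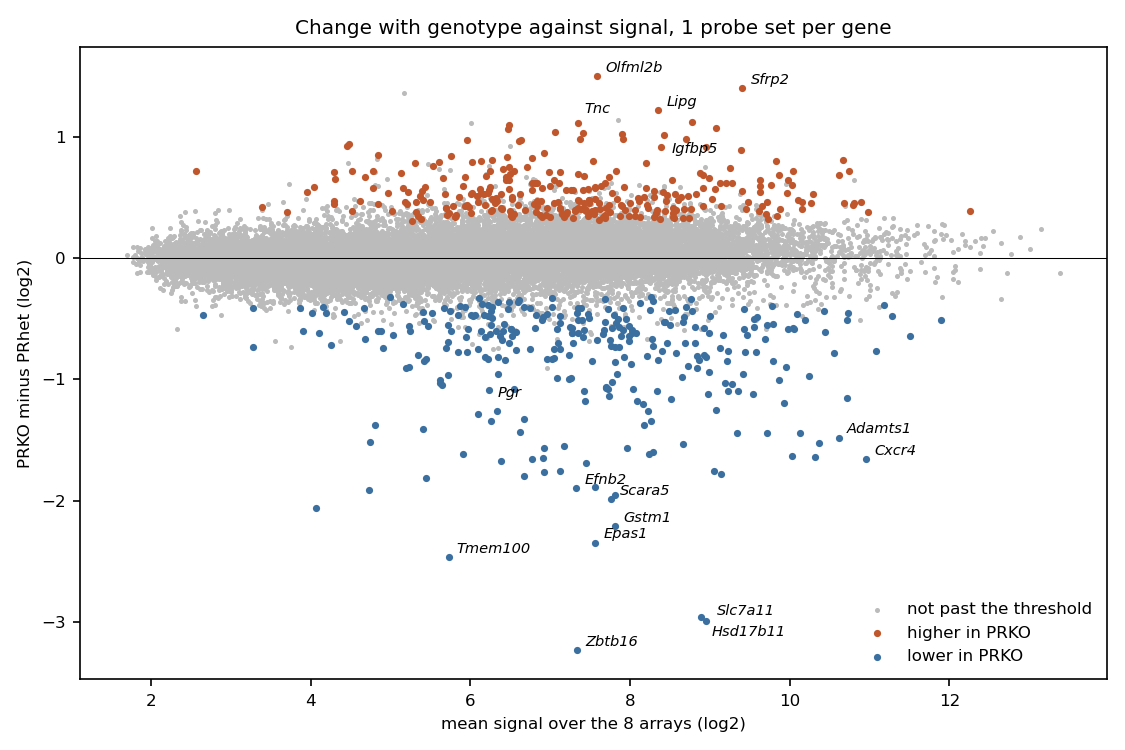
Log2 difference between PRKO and PRhet (vertical) against the mean log2 signal over the 8 arrays (horizontal), one point per gene; coloured points passed the limma threshold, blue lower and orange higher in PRKO. The largest downward change, at -3.23, is Zbtb16, and the largest upward change that passed is Olfml2b, a 2.83-fold difference.

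Of 26 measured genes that earlier work tied to PR in periovulatory follicles, 13 fell, 0 rose and 13 did not pass the test. Adjusted over the list alone, 15 fell. Besides Zbtb16 and Epas1, the lower genes included Cxcr4, a chemokine receptor (-1.65 ± 0.13, SE), Cldn1, a tight junction protein (-1.52 ± 0.18), the metallothionein gene Mt2 (-1.52 ± 0.19) and the matrix protease Adamts1 (-1.48 ± 0.13), with limma adjusted p from 6.20e-05 to 0.00132. Adamts1 went from 11.35 ± 0.28 to 9.87 ± 0.16 (SD, n = 4), a 2.79-fold drop. The others were Snap25 (-1.43), Pparg (-1.35), Sphk1 (-1.26), Prkg2 (-0.99), Mt1 (-0.97), Per1 (-0.64) and Ctsl (-0.64). Il6 (-0.73 ± 0.23, limma adjusted p = 0.130), Cited2 (-0.28) and Abcb1b (0.22) did not pass. The list as a whole was lower than other genes (camera adjusted p = 1.15e-14 with a preset correlation, adjusted p = 0.447 with an estimated correlation). The Snap25 call ended without PRhet replicate 1 or 3 or PRKO replicate 2 or 3, at limma adjusted p up to 0.0754. Areg was not analysed here.

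In the list of cumulus expansion and matrix genes, 3 of 20 measured members fell, Adamts1, Adamts5 (-0.75 ± 0.12) and Pgr, and none rose. Bgn (0.52), Cd44 (0.44) and Vcan, the versican proteoglycan that ADAMTS1 cleaves (-0.33 ± 0.10, limma adjusted p = 0.0985), did not pass, nor did the hyaluronan-binding protein gene Tnfaip6 (0.16 ± 0.21). Adjusted over the list alone, 3 members rose and 5 fell. Camera tested the list as lower at adjusted p = 0.381, and its mean was -0.118 while its median was 0.005. That p was 0.0338 among probe sets at or above the median signal (mean -0.22) and 0.0312 with theca and stroma markers as a covariate (-0.23), against adjusted p = 0.773 with an estimated correlation. Among EGF-like ligands and MAPK response genes, Egfr, the receptor of those ligands, fell by 1.16 ± 0.15 (limma adjusted p = 0.00144) and Fosl2, a subunit of the AP-1 transcription factor, rose by 0.64 ± 0.12 (0.0164). The other 24 of 26 did not pass (2 higher and 2 lower over the list alone; camera adjusted p = 0.381, and 0.0368 without PRhet replicate 2; adjusted p = 0.773 with an estimated correlation), and the Fosl2 call ended without PRhet replicate 2 or PRKO replicate 2 or 3 (adjusted p up to 0.0632). Of 17 prostaglandin genes, the transporter Slco2a1 fell by 1.76 ± 0.19 (limma adjusted p = 0.000458), from 7.81 ± 0.46 to 6.05 ± 0.23, and the receptor Ptgfr rose by 0.43 ± 0.10 (0.0418), while Hpgd, the enzyme that degrades prostaglandins, was at -0.38 ± 0.11 (0.112). Adjusted over that list alone 1 rose and 2 fell; camera tested it as higher at adjusted p = 0.875, and its median was 0.074 while its mean was -0.057.

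Of 19 steroidogenesis and gonadotropin response genes, 2 fell, 2 rose and 15 did not pass; adjusted over the list alone, 3 fell and 3 rose. The follicle-stimulating hormone receptor gene Fshr fell by 1.06 ± 0.15 (SE) and Cebpb, a transcription factor of luteinisation, by 0.57 ± 0.10, with limma adjusted p of 0.00221 and 0.00966. Hsd17b7 rose by 0.60 ± 0.09 (limma adjusted p = 0.00300), and Cyp11a1, the side-chain cleavage enzyme, by 0.39 ± 0.09 (0.0324). The camera adjusted p of that list was 0.626. In the cholesterol synthesis and uptake list, 16 of 18 measured genes had positive differences, but 0 passed in limma, over all genes or over the list alone, and 7 had an unadjusted p under 0.05. Lss (0.37 ± 0.11), Sc5d (0.29) and Cyp51 (0.28) had the largest, with limma adjusted p of 0.115, 0.192 and 0.196. Their median was 0.182, and the list was higher than other genes with the preset correlation (camera adjusted p = 0.00171; adjusted p = 0.773 with an estimated correlation). The Ptgfr call ended without any 1 array other than PRhet replicate 1 or PRKO replicate 1 (limma adjusted p 0.0855 to 0.126), and the Cyp11a1 call without any 1 other than PRhet replicate 4 or PRKO replicate 1 (0.0604 to 0.0923).

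Protease and inhibitor genes changed in both directions: 4 of 27 rose, 5 fell and 18 did not pass (5 and 6 over the list alone). The lower ones were Adam8, a membrane metalloprotease (-1.79 ± 0.16, limma adjusted p = 0.000154), Adamts1, Mmp19 (-0.80), Adamts5 and the cathepsin gene Ctsl. Tissue and urokinase plasminogen activator genes rose, Plat by 0.91 ± 0.09 and Plau by 0.72 ± 0.13 (limma adjusted p = 0.000244 and 0.0118), as did Timp3 (0.58) and Ctsz (0.54). Camera tested the list as higher (adjusted p = 0.890) and fry as lower (adjusted p = 0.884), its median was 0.063 and its mean -0.048, and the Mmp19 call ended without PRhet replicate 3 (limma adjusted p = 0.0541). Of 30 adhesion and migration genes 2 fell, Cxcr4 and Cldn1, and 28 did not pass (1 higher and 3 lower over the list alone; camera adjusted p = 0.381, and 0.0145 with theca and stroma markers as a covariate; adjusted p = 0.773 with an estimated correlation). Of 22 exocytosis genes Snap25, a vesicle fusion protein, alone passed, from 7.34 ± 0.66 to 5.91 ± 0.45 (1 over the list alone; camera adjusted p = 0.591). Among 34 cytokine and chemokine genes Cxcr4 alone passed, with 2 lower over the list alone, and Lif (-0.38) and Il6 did not pass (tested as lower, camera adjusted p = 0.381, with a mean of -0.08 and a median of 0.012; 0.0338 among probe sets at or above the median signal, with a mean of -0.29; adjusted p = 0.773 with an estimated correlation). The complement regulator Cd55 rose by 0.73 ± 0.13 (limma adjusted p = 0.0101) as the 1 of 25 Toll-like receptor and complement genes that passed, with 3 higher over the list alone, and Ly96 was at 0.74 ± 0.18 (0.0587; camera adjusted p of the list = 0.470). Of 19 interferon-stimulated genes 0 passed in limma, over all genes or over the list alone, and 3 had an unadjusted p under 0.05 (camera adjusted p = 0.381); Rtp4 (0.36) and Xaf1 (0.32) had the largest differences, with limma adjusted p of 0.200 and 0.0958.

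Of 19 hypoxia-inducible genes, Epas1 and the mitochondrial protein gene Bnip3 (-0.52 ± 0.11) fell, while the prolyl hydroxylase gene Egln3 (0.78 ± 0.14) and the peptide hormone gene Adm (0.75 ± 0.13) rose, with limma adjusted p from 1.43e-05 to 0.0309. Vegfa (0.18) and Slc2a1 (0.36) did not pass, 2 rose and 3 fell over the list alone, and the camera adjusted p was 0.616. Hk2, a hexokinase, was the 1 of 16 glycolysis genes that passed, also over the list alone, and rose by 0.64 ± 0.11 (limma adjusted p = 0.0102; camera adjusted p of the list = 0.0779, and 0.0221, 0.0415 and 0.0167 without PRhet replicate 2, PRhet replicate 4 and PRKO replicate 1; adjusted p = 0.773 with an estimated correlation). In the circadian clock list, Rora, a nuclear receptor that drives Arntl, fell by 1.07 ± 0.19 and Per1 by 0.64 ± 0.11 (limma adjusted p = 0.00963 and 0.0109), while Ciart (-0.46), Nfil3 (-0.45) and Cry1 (-0.29) did not pass. Over the list of 17 alone 5 fell and 0 rose, and the list was lower than other genes (camera adjusted p = 0.00397; adjusted p = 0.486 with an estimated correlation). Per1 is also in the PR-associated list. Of 24 proliferation genes the cell cycle inhibitor gene Cdkn1b rose by 0.33 ± 0.07 (limma adjusted p = 0.0346; 1 over the list alone; camera adjusted p = 0.381, and 0.0440 without PRhet replicate 1, with a mean of -0.09; adjusted p = 0.773 with an estimated correlation). Of 19 apoptosis genes Casp9 rose by 0.35 ± 0.07 (0.0307; 1 higher and 1 lower over the list alone; camera adjusted p = 0.470). Of 16 steroid receptor and coregulator genes Paqr8, a membrane progestin receptor, fell by 0.47 ± 0.07 (limma adjusted p = 0.00428; 1 over the list alone), and Nrip1 (0.39) and Esr1 (-0.20) did not pass; camera tested the list as lower at adjusted p = 0.852, with a mean of -0.002 and a median of 0.003. The limma call of Bnip3 ended without any 1 array other than PRhet or PRKO replicate 4 (adjusted p 0.0530 to 0.0914), that of Casp9 without any 1 other than PRhet replicate 1 or PRKO replicate 2 (0.0582 to 0.0894), and that of Cdkn1b without any 1 other than PRKO replicate 4 (0.0680 to 0.104). With the mean of theca and stroma markers, 0.19 higher in PRKO, as a covariate, these 3 genes and Egln3, Hk2, Fosl2, Mmp19 and Cyp11a1 did not pass (limma adjusted p 0.0570 to 0.153). Standard errors were wider there, while the differences were 0.34 for Casp9, 0.34 for Cdkn1b, 0.75 for Egln3, 0.67 for Fosl2, 0.44 for Cyp11a1, 0.54 for Hk2, -0.73 for Mmp19 and -0.40 for Bnip3.

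**Figure D3:**
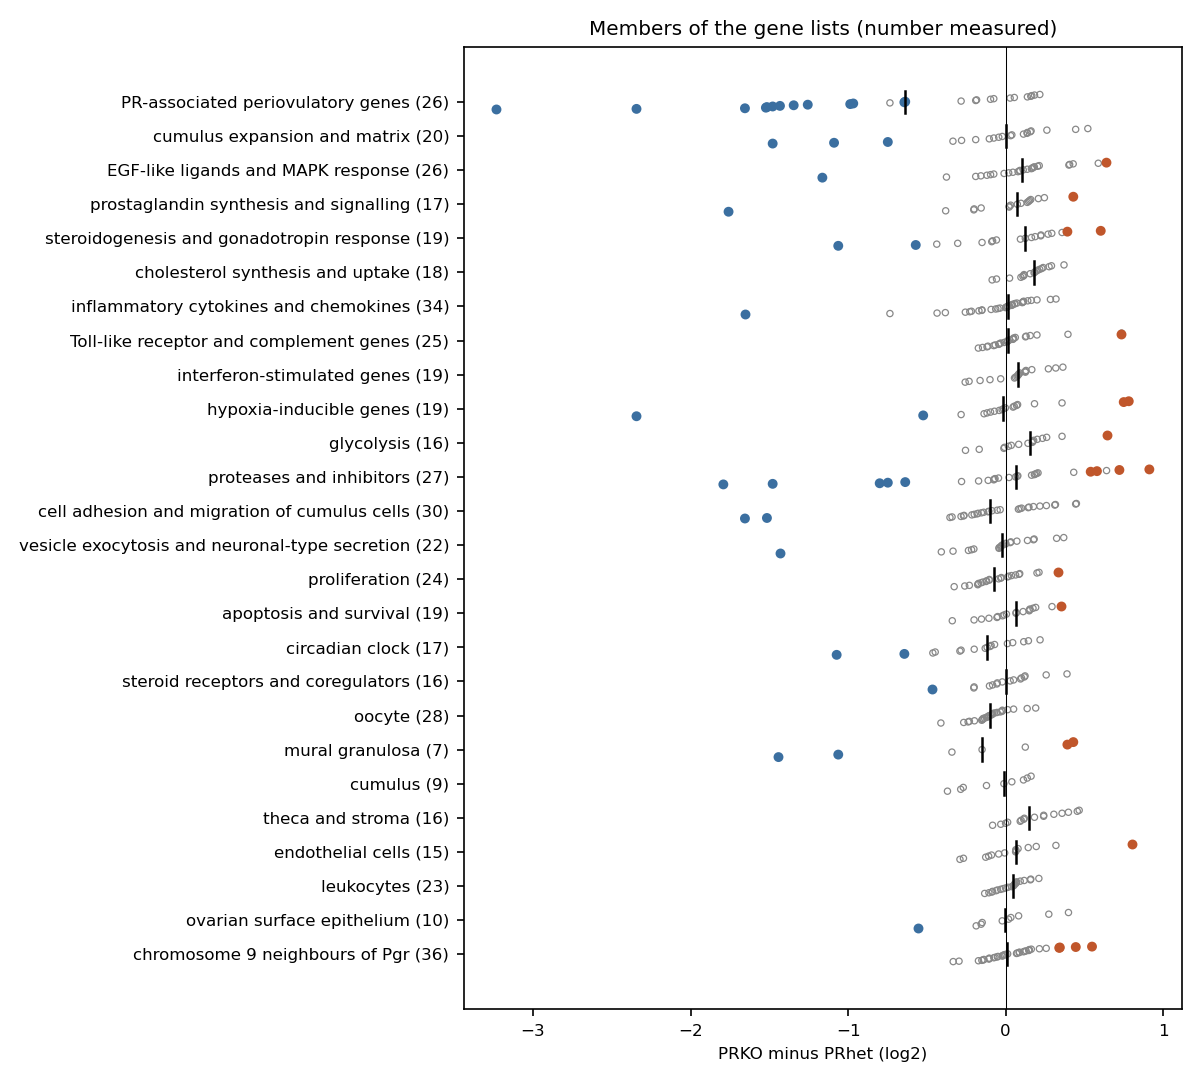
Log2 difference between PRKO and PRhet of each measured member of the 26 gene lists; filled points passed the limma threshold (blue lower, orange higher), open points did not, and black lines are medians. The list of PR-associated genes has 13 filled points, all lower, while the proteases have 4 higher and 5 lower.

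Markers of the cells a complex could hold or carry along were listed too. Of 28 oocyte genes and 9 cumulus genes 0 passed in limma, over all genes or over the list alone, and 2 and 1 had an unadjusted p under 0.05. In the oocyte list 24 of 28 differences were negative; Uchl1 was at 0.14 and Padi6 at -0.11, and Kit had the largest difference (-0.41, limma adjusted p = 0.148). The oocyte marker mean differed by -0.10 ± 0.20 (SE), while single arrays spanned 5.75 to 6.50, and camera gave the list an adjusted p of 0.122. That p was 0.000122 without PRhet replicate 1 (mean -0.22), 0.0286 without PRhet replicate 3 (-0.14) and 0.00184 without PRKO replicate 4 (-0.19), and the mean was 0.03 without PRhet replicate 4 (0.952). Over all arrays it was adjusted p = 0.773 with an estimated correlation. The cumulus markers Tnfaip6 and Sult1e1 were at 0.16 and 0.14 (camera adjusted p of the list = 0.470, and 0.0440 with a mean of -0.19 without PRhet replicate 1; adjusted p = 0.773 with an estimated correlation), with Npr2 at -0.37 and limma adjusted p of 0.222. Of 7 mural granulosa genes 2 fell, Cd34 (-1.44 ± 0.17) and Fshr, and 2 rose, Cyp11a1 and Ptgfr, also over the list alone, while Star was at -0.15 (camera adjusted p = 0.381).

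Of 16 theca and stroma genes 0 passed in limma, over all genes or the list alone, and 5 had an unadjusted p under 0.05. Acta2 (0.47), Tagln (0.45) and Col3a1 (0.40), genes of smooth muscle and collagen, were among 13 with positive differences (limma adjusted p of 0.280, 0.0834 and 0.205). That list was higher than other genes (camera adjusted p = 0.0134; adjusted p = 0.773 with an estimated correlation), with adjusted p = 0.193 without PRhet replicate 2 and 0.221 without PRKO replicate 1. Of 15 endothelial genes the growth factor receptor Kdr rose by 0.80 ± 0.15 (limma adjusted p = 0.0126; 1 over the list alone; camera adjusted p = 0.852), at an adjusted p of 0.0508 without PRhet replicate 3 and 0.0512 without PRKO replicate 3, while Egfl7 was at 0.08. Of 23 leukocyte genes 0 passed in limma over all genes, over the list alone or at an unadjusted p under 0.05, with Cd68 at 0.21 and Cx3cr1 at 0.07 (limma adjusted p of 0.418 and 0.862; camera adjusted p = 0.637). Of 10 surface epithelium genes Wt1, a transcription factor that granulosa cells also express, fell by 0.56 ± 0.11 (limma adjusted p = 0.0149; 1 over the list alone) and Krt8 was at 0.03, with a camera adjusted p of 0.588. The Wt1 call ended without PRhet replicate 3 or PRKO replicate 2 or 3, at adjusted p up to 0.0587. Erythrocyte markers were too few to test.

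Genes near Pgr on chromosome 9, where DNA linked to the mutated allele could differ between genotypes, were followed as a separate list. Of its 36 measured genes 4 rose in PRKO and 0 fell, also over the list alone. Endod1 rose by 0.55 ± 0.08 (SE, limma adjusted p = 0.00263), Cfap300 by 0.44 ± 0.10 (0.0309), Aasdhppt by 0.34 ± 0.08 (0.0467) and Sesn3 by 0.34 ± 0.08 (0.0479). Maml2 (-0.30), Tmem123 (0.26) and Trpc6 (-0.33) did not pass, and the list's camera adjusted p was 0.381, with a median of 0.007. The Endod1 call held without any single array, whereas Cfap300 lost its call without any 1 array other than PRhet or PRKO replicate 4 (limma adjusted p up to 0.0992), Aasdhppt without any 1 other than PRhet or PRKO replicate 1 (up to 0.125) and Sesn3 without any 1 of the 8 (up to 0.135). With the theca and stroma marker mean as a covariate these 3 did not pass (0.143, 0.0954 and 0.158), at differences of 0.38 ± 0.11, 0.37 ± 0.10 and 0.33 ± 0.10 (SE).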

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

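The tests of oocyte RNA, of theca and stroma cells and of neighbours in other splits were chosen after the results were seen; neighbouring genes that passed were noticed before the other tests of adjacent genes were written, whose counts had not been seen, and the split test was set beforehand.

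The 582 genes past the threshold between genotypes include transcripts as different as Zbtb16, Slc7a11 and Sfrp2. Of the 35 splits of the 8 arrays into 4 and 4, 1 gave as many genes, the genotype split itself, and the highest other gave 0. The other splits were fitted without genotype, so a genotype difference adds to their residual and lowers their counts. The genotype split ranks highest of the 35, but chance is not excluded. An uneven share of oocyte RNA between arrays is argued against, since 93.8% of the genes stayed past the threshold with the oocyte marker mean as a covariate. An effect of the receptor's loss is a hypothesis that these tests leave, beside more stroma for the genes higher in PRKO. Other differences between the litters or animals of each genotype were not tested.

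The genes higher in PRKO include matrix and secreted protein genes that stromal cells also express, such as Tnc and Igfbp5, so more theca and stroma cells in the PRKO complexes could raise them. The theca and stroma marker mean was 5.643 in PRhet and 5.828 in PRKO, and with it as a covariate 106 of the 286 genes higher in PRKO stayed past the threshold, 7 of them among the 12 at least 2-fold higher. The median rise of the 286 was 0.49 before and with the covariate, and the standard error was wider for 272 of them, with a median of 0.10 before and 0.11 after. Of the 12, Tnc lost its call by a smaller difference (1.11 ± 0.22 before, 0.80 ± 0.22 after), Igfbp5 (1.02 ± 0.21, then 0.93 ± 0.26), Igfbp6 (1.03 ± 0.19, then 0.93 ± 0.23) and Usp17ld (1.07 ± 0.24, then 0.94 ± 0.29) by a smaller difference with a wider standard error, and Msc (1.10 ± 0.26, then 1.24 ± 0.32) by a wider standard error. With the covariate 149 of the 286 rises were smaller and the median stayed. The rule for this test counted against more stroma only if at least as many calls stayed as were lost. Otherwise it counted for more stroma only if the median rise also fell by more than the median standard error. Neither outcome was met, so more stroma stays open for the rises as a set. For single genes such as Tnc, more stroma and an effect of the receptor's loss cannot be told apart. The markers with the highest signal (Ptch1 at 7.79 in both genotypes, Acta2 at 7.02 in PRhet and 7.49 in PRKO) could hide a small share. No sort or gate that would remove such cells is given in the sources used here.

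Genes that lie next to each other often passed together, such as Hsd17b11 with Nudt9 (-2.96 and -1.53), Slc7a11 with Pcdh18 (-2.99 and -1.18) and Lipg with Acaa2 (1.22 and 0.51). There were 51 adjacent pairs among 569 called coding genes. The median of 10000 placements within deciles of signal was 20 (one-sided permutation p = 0.0001, the smallest they can give). Without related or overlapping neighbours there were 41 against 17 (permutation p = 0.0001). These counts argue against chance placement, and against related or overlapping neighbours as the source of all pairs. Relatedness was judged by gene name and overlap by gene position. Probe sequences were not examined, so shared probes stay open. Of all pairs 2% lay around Pgr, which argues against a chromosome segment there as the source of most pairs. Segments elsewhere were not tested. Of the 41 pairs 35 changed in the same direction, against 20 by chance (one-sided permutation p = 0.0001). Among 18 splits with 2 arrays of each genotype on each side, an equal number of top-ranked genes gave at most 19 such pairs. Those splits leave genotype in the residual, so genes that respond to it rank low there. Neighbours that vary together in any comparison are therefore not excluded. Shared local regulation may underlie such pairs, a hypothesis noticed and tested on the same data. Plxna2 with Cd34 (0.52 and -1.44) and Mfge8 with Abhd2 (0.40 and -1.64) went opposite ways.

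Among 338 sets of 4 arrays, 24 held an array far from the other 3 by Dixon's test at its 95% critical value, and chance gives about 1 in 20, or 16.9. PRhet replicate 4 was the lowest in 8 of them: Adamts1 at 10.93 (others 11.45 to 11.55), Adm at 5.81 (6.20 to 6.25), Ciart at 5.48 (others 5.57), Cx3cr1 at 5.00 (5.49 to 5.58), Il6 at 3.31 (4.33 to 4.48), Nfil3 at 8.92 (9.38 to 9.44), Timp1 at 10.03 (10.59 to 10.70), and the mean of the PR-associated list at 8.64 (8.99 to 9.05). PRhet replicate 1 was high for Abcb1b at 9.54 (9.07 to 9.13) and Bak1 at 7.35 (6.98 to 7.04) and low for Emcn at 3.90 (4.15 to 4.19). PRhet replicate 2 was low for Cfap300 at 4.36 (4.69 to 4.72), and PRhet replicate 3 high for Usp17ld at 9.43 (8.17 to 8.32). PRKO replicate 1 was high for Sfrp2 at 10.79 (9.79 to 9.93) and Per1 at 7.84 (7.45 to 7.49) and low for Gstm1 at 6.48 (6.77 to 6.80) and Trpc6 at 6.09 (6.76 to 6.81). PRKO replicate 2 was low for Hk2 at 10.02 (10.36 to 10.42) and high for Usp17ld at 9.99 (9.43 to 9.52). PRKO replicate 4 was low for Fosl2 at 9.58 (10.03 to 10.10) and Rtp4 at 5.37 (5.83 to 5.90), and high for Rrm2 at 8.61 (8.06 to 8.11), Slc2a1 at 10.26 (9.46 to 9.53) and the cumulus list mean at 8.27 (7.90 to 7.96). The 13767 probe sets with several gene symbols or none were left out of the comparison. In a separate limma fit adjusted over all 35556 probe sets, 71 of them had an adjusted p under 0.05, 25 higher and 46 lower in PRKO. In that fit 206 genes with a single symbol passed, against 582 in the comparison.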

How the results depend on the processing

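The covariates (oocyte markers, theca and stroma markers, first component within genotypes) were chosen after the data were seen. No result past its threshold turned direction under any alternative run. The count of 582 genes was 106 without moderation, 206 with all probe sets, 932 at an adjusted p under 0.1, 324 with the theca and stroma covariate (286 of them among the 582) and 301 to 532 with single arrays left out. It was 671 with the replicate block, 510 of them among the 582; with the block Casp9, Cdkn1b, Ptgfr, Aasdhppt and Sesn3 did not pass, while Ly96, Cd59a, Lif, Tagln, Cd44 and Egr2 did. Arrays that share a replicate number correlated at 0.08 to 0.153 after removing genotype means, 3 of the 4 pairs over 0.1, and 4 of the 8 arrays correlated best with their own number, a hint from the data and not the design. The count was 514 after quantile normalization (483 of them among the 582). The 286 higher and 296 lower genes were 206 and 308 after quantile normalization, 63 and 143 with all probe sets, 128 and 196 with the theca and stroma covariate and 115 and 186 without PRKO replicate 3, while 502 were higher and 430 lower at an adjusted p under 0.1. The 325 genes by unadjusted p and fold were 89 at a fold of at least 2 and 308 to 390 with single arrays left out. The Pgr difference of -1.09 had an adjusted p of 0.0753 with an intensity trend, 0.247 without moderation (-1.09 in both) and 0.0824 with the theca and stroma covariate (-1.22); it was -1.32 to -0.90 with single arrays left out, and over its alternatives adjusted p ran from 0.00113 to 0.247. The 4 gene lists past the threshold were 0 with an estimated correlation, 1 with fry, 7 with the theca and stroma covariate and 4 to 7 with single arrays left out. The stricter or looser thresholds move counts by construction, fewer arrays give less precision, and unmoderated tests have fewer degrees of freedom; for the rest the cause was not tested. Of the 60 named genes past the threshold, 20 stayed past it in every alternative run on them, 38 lost it without moderation and 18 with some array left out. After quantile normalization Cyp11a1, Cdkn1b, Usp17ld, Ptgfr, Aasdhppt, Sesn3 and Msc did not pass, and Msc did not after centring. Of 1527 values of the 82 other named genes 39 passed. The glycolysis list passed with each of the 3 covariates, and the oocyte list with array weights (camera adjusted p = 0.0481) and the theca and stroma covariate. The theca and stroma list did not pass among probe sets at or above the median signal (camera adjusted p = 0.416) or lower quartile (0.0689). Background signal was not analysed here, so signal over background is not known.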

Other observations

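The groups described here were assembled after the gene values were seen, while the tests of their remaining members were written before those members were examined. The test of the genes around Pgr was chosen after 4 of them were seen to pass.

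Of 42 measured genes of glutathione supply and oxidative stress, 9 fell, 1 rose and 32 did not pass in limma. The 9 were the cystine carrier Slc7a11, Gstm1, Mt1, Mt2, Gsta4 (-0.51), Gclc, the catalytic subunit of the enzyme that starts glutathione synthesis (-1.10 ± 0.13, SE, adjusted p = 0.000633), the glutathione transferase genes Gstm3 (-1.81 ± 0.17, adjusted p = 0.000194) and Gstm2 (-1.55), and Osgin2 (-1.19), while Oplah rose by 0.51. Of 28 genes that glucocorticoids induce in many tissues 9 fell and 0 rose, among them Tsc22d3 (-1.76 ± 0.20, adjusted p = 0.000633), Glul, the glutamine synthetase gene (-1.44 ± 0.20, adjusted p = 0.00266), Ddit4 (-1.10) and Klf9 (-0.86); Zbtb16, Per1, Mt1 and Mt2 also count among the 9 and stand in the PR-associated list, and Mt1 and Mt2 in the glutathione group too, while Fkbp5 was at 0.03 and did not pass. The Gstm and Mt genes are neighbours of like sequence, which the probe sets may not keep apart; of the 51 adjacent pairs, 41 were without related or overlapping neighbours.

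Of 19 genes of the insulin-like growth factor axis 5 rose, 0 fell and 14 did not pass, among them Igf1r (-0.29) and Stc1 (0.61). Those that rose were Pappa, a protease that cleaves the binding proteins (0.74 ± 0.13, adjusted p = 0.00963), Ghr (0.70), Igfbp4 (0.60), Igfbp5 and Igfbp6. The theca and stroma marker mean was 0.19 higher in PRKO too (camera adjusted p = 0.0134, adjusted p = 0.773 with an estimated correlation). With it as a covariate Igfbp5 (0.93 ± 0.26, adjusted p = 0.114) and Igfbp6 (0.93 ± 0.23, adjusted p = 0.0800) did not pass, and Igfbp5 did not without PRhet replicate 3 or PRKO replicate 1, 2 or 3 (adjusted p up to 0.0819). Of 68 Eph, semaphorin and slit guidance genes 10 rose and 1 fell, with Rgmb (0.98 ± 0.10, adjusted p = 0.000383), Sema3d (0.80) and Slit2 (0.75) higher and Efnb2 lower.

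One hypothesis was that each whole group moves, beyond the genes that prompted it. It was tested with camera and an estimated correlation on the members outside the 150 largest changes per direction. The 33 remaining glutathione and oxidative stress genes had a median of 0.044 and camera gave 0.945 before and after adjustment over the 4 groups. For the 21 remaining glucocorticoid-induced genes the median was -0.067, for the 14 of the growth factor axis 0.034 and for the 58 guidance genes 0.029. Camera gave these 3 groups 0.403, 0.641 and 0.541 before adjustment (adjusted p = 0.855 for each). For the glutathione group a median at or above 0 was the outcome set beforehand as counting against the hypothesis. Setting the largest changes aside takes out most of the genes that passed, so that outcome is weak. The hypothesis stays open for the other 3 groups. A chromosome segment around Pgr, carried along with the mutated allele, was tested on 81 coding genes around it. Of these 4 passed (4.94% against 3.06% elsewhere), all higher in PRKO, and a one-sided Fisher's exact test gave p = 0.237. With so few genes this window cannot tell a linked effect of the segment from the rate elsewhere. In the list of neighbours set beforehand 4 of 36 passed, against 2.92% of all genes, with a camera adjusted p of 0.381. Fry for change in either direction gave that list an adjusted p of 2.53e-11, the smallest of the 26 lists. The next was 9.54e-09 by the same fry test, for Toll-like receptor and complement genes, and most other lists passed it too. A linked effect therefore stays open.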
